A study of Homo sapiens with 8 samples.

How the data were processed

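RNA from 8 human skin samples labelled as actinic keratosis was sequenced. Per the labels' protocols, total RNA was isolated with a column shredder and phenol reagent, treated with DNase, and made into libraries with an Illumina mRNA kit; reads were paired-end from an Illumina HiSeq instrument. The labels name the molecule as polyA RNA, although RNAs without a polyA tail, such as 7SL and 7SK, took 10.14 to 17.24% of the counts in genes. The deposited table holds estimated counts per Ensembl transcript, with decimals, for 236186 transcripts in 8 columns, and all 8 were used. Per the submitters' processing notes the genome build was hg38; the quantifier, its version and the transcript annotation are not given in the sources used here. Of the deposited values above 0, 14.55% were whole numbers within a tolerance of 0.0005, which fits estimated rather than whole-read counts.

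Transcripts were summed to genes through GENCODE release 29 by the ID without its version. Of the transcripts, 203876 (86.32%) matched, 180508 of them with the same version, giving 58165 genes, of which 57827 had a current symbol. The other 32310 transcripts held 2.84 to 4.43% of each library and stayed out of library sizes and tests. Gene sums were rounded to whole numbers, as estimated counts need not be whole. Library totals ran from 44280014 to 77748599 estimated counts. At this depth the Wilson 95% interval of a share such as that of FLG was at most 0.0098 percentage points wide, and 3 counts, the limit that a count of 0 allows, were 0.0445 to 0.0639 CPM. These intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

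The samples form 1 group, so there was no comparison between groups and no paired or split-sample test. Replicates were numbered 1 to 8 in the order of the sample records; the numbers only name samples, and whether that order follows a batch is not given in the sources used here. Before the data were examined, 33 gene lists with 334 genes, 20 pairs of lists, 20 within-lesion comparisons, the tests and the rule for named genes were fixed. The rule named the 3 members of each list with the highest mean CPM, the 20 genes with the highest mean CPM that are neither mitochondrial nor ribosomal protein genes, the 20 genes with the largest ratio of quasi-dispersion to its prior among genes called variable in every fit, and every gene of the within-lesion comparisons. As no gene was called, the third part named none, and the variable genes in the text were chosen after their values were seen. Some genes that the rule named are not reported here. Genes whose level can show a person's sex or inherited genotype were left out of naming, as were immunoglobulin, T cell receptor and HLA genes. Of the list genes, 324 reached a mean count of 10 and entered the tests; 1 list gene was not analysed here.

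Counts were normalised with TMM factors in edgeR 4.0.16 (R 4.3.3) and expressed as CPM, and log2 CPM carried a prior count of 2. Genes with a mean count of at least 10 were tested, 21424 in all, 16142 of them coding. Variability between lesions was tested with edgeR's quasi-likelihood fit (intercept only, robust, 7 residual degrees of freedom): the quasi-dispersion over its abundance-trended prior was referred to an F distribution, one-sided, with Benjamini-Hochberg adjustment at 0.05. The prior degrees of freedom were 3.82 and the common biological coefficient of variation 52.4%. The test of each gene against the trend alone, with a chi-square distribution, was added after the data were seen. Alternatives were limma 3.58.1 on log2 CPM, DESeq2 1.42.0 dispersion outliers and size factors, upper-quartile scaling, no count filter and a minimum of 50. List variability was set against 10000 random lists matched on size and expression. Genes of a list vary together, so the p of a list is too small.

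List scores were means of log2 CPM over tested members. Within-lesion comparisons used log2 CPM per kb, with lengths averaged over the transcripts of a gene in proportion to their abundance, and an exact two-sided sign-flip test over 256 sign patterns. Correlations used exact two-sided permutation tests over 40320 orders of the lesions, with r repeated without the 2 lesions farthest from the median of x. Where lesions fell into separate clusters no pooled r was given, and r within a cluster of at least 6 lesions was added after the data were seen. A correlation given another measure permuted residuals, so its p is approximate. Adjustment was over 20 comparisons and 20 pairs. Outside these, 2 relations of the T cell score were adjusted over themselves, and relations with library measures over 17. Each result was recomputed with each replicate left out; these runs kept the TMM factors of the full data for scores, comparisons and correlations and recomputed them for the variance fits. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for these steps, and matplotlib 3.10.9 for figures.

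The variance test was tested on simulated counts for the 21424 genes and library sizes seen here. Where genes shared the trend, edgeR's test recovered 34.5% of 200 genes with 4-fold and 80.5% of 200 with 10-fold raised dispersion; with the spread fitted here it recovered 0% of 200 genes with 10-fold raised dispersion, and the trend test 95.5%, with 4080 calls in all, most of them genes that had not been changed. The permutation functions were tested on 300 simulated sets of 8 values: 4.0% of null correlations and 5.3% of null differences passed 0.05, against 93.3% of correlations of 0.9 and 99.3% of differences of 2 SD.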

Results

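Bulk RNA sequencing was analysed from 8 human skin samples, all labelled as actinic keratosis, a sun-induced precancerous lesion of the epidermis. They form 1 group, without a control group among the samples used here, so the values describe what the lesions expressed and how they differed from each other, not what distinguishes them from healthy skin. The numbers 1 to 8 follow the order of the sample records and only name the lesions. The labels do not state that they came from separate donors, so p-values measure only the spread between these samples, which may be technical in part. The libraries held 44280014 to 77748599 estimated counts, of which 95.57 to 97.16% fell in annotated genes, and 18970 to 22189 genes reached a count of 10. Of the counts in genes, 79.55 to 84.27% lay in coding genes, 10.14 to 17.24% in 7SL, 7SK, RMRP and RPPH1 RNA, 0.25 to 0.83% in mitochondrial genes and 0.23 to 3.32% in the nuclear RNAs MALAT1 and NEAT1. No 2 libraries agreed within sampling noise: the chi-square statistic per gene lay between 154.5 and 643.5 over the 28 pairs, and Spearman's rho across genes between 0.909 and 0.968.

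Levels in this paragraph are CPM without correction for length, which raises long transcripts. Among coding genes, the highest mean CPM belonged to FLG, which encodes the granular-layer protein filaggrin, at 16670 ± 11210 CPM (SD, n = 8). Per kb FLG was not highest: its mean log2 CPM per kb was 10.13, against 13.01 for S100A9, 12.04 for KRT14 and 11.35 for KRT5. FLG was followed in CPM by the stress keratin KRT6A at 10250 ± 9948 CPM, the basal keratin KRT14 at 7913 ± 4711 CPM and the desmosome gene DSP at 7649 ± 2991 CPM. KRT16 reached 7319 ± 7502 CPM (4805 CPM without lesion 8), the suprabasal keratins KRT10 and KRT1 6922 ± 4611 and 5487 ± 2571 CPM, and the basal keratin KRT5 6540 ± 2296 CPM. FLG2 stood at 6057 ± 4188 CPM, the alarmin gene S100A9 at 5963 ± 4357 CPM, AHNAK at 5680 ± 1314 CPM, the desmoglein gene DSG1 at 5456 ± 2626 CPM, KRT6B at 5238 ± 4793 CPM and KRT17 at 4149 ± 4010 CPM. The noncoding RNAs RN7SL1 and RN7SL2, the RNA of the signal recognition particle, and RN7SK lay above all other genes listed here, at 55040 ± 26200, 45230 ± 19620 and 27970 ± 4766 CPM. SNORD3A stood at 9652 ± 4030 CPM, RPPH1 at 8804 ± 4162 CPM and MALAT1 at 7460 ± 4815 CPM. In the hg38 annotation FLG lies on chromosome 1 (152302175 to 152325203), KRT6A on chromosome 12 (52487174 to 52493257), and KRT14, KRT16 and KRT17 on chromosome 17 (41582279 to 41586921, 41609778 to 41615899 and 41619441 to 41624842). Members of the KRT6, KRT14/KRT16/KRT17 and RN7SL families resemble each other in sequence, so the division of reads among them is uncertain.

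Of the epidermal lists, the suprabasal list scored highest, at 11.10 ± 0.75 mean log2 CPM (SD, n = 8), and varied 4.11-fold between the lowest and highest lesion. The stress keratinocyte list, made of hyperproliferation-associated keratins, alarmins and small proline-rich proteins, scored 10.16 ± 1.16 and varied 15.5-fold. Its lowest score was 8.06 in lesion 7 and its highest 12.02 in lesion 8. KRT6A ran from 2361 to 33530 CPM and KRT17 from 553.5 to 13350 CPM between those same lesions. The granular and cornified list scored 8.93 ± 0.62, with IVL, a cornified envelope precursor, at 633.7 ± 612.3 CPM. The basal list scored 8.75 ± 0.39, with COL17A1 of the hemidesmosome at 1604 ± 963.7 CPM. Lesion 7, lowest for stress genes, had the highest FLG, KRT10 and KRT1 levels, at 41640, 17510 and 11190 CPM. Its suprabasal score was the highest too, at 12.26. The granular and cornified score, however, peaked in lesion 8, highest for stress genes, at 9.92 against 9.50 in lesion 7. The IL-17 and IL-36 list scored 2.35 ± 0.61, led by IL36RN at 201.5 ± 118 CPM, the neutrophil chemoattractant CXCL8 at 78.6 ± 107.4 CPM (45.1 CPM without lesion 7) and IL36G at 77.97 ± 63.2 CPM. IL17A had 0 to 6 counts per library and was not tested.

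**Figure D1:**
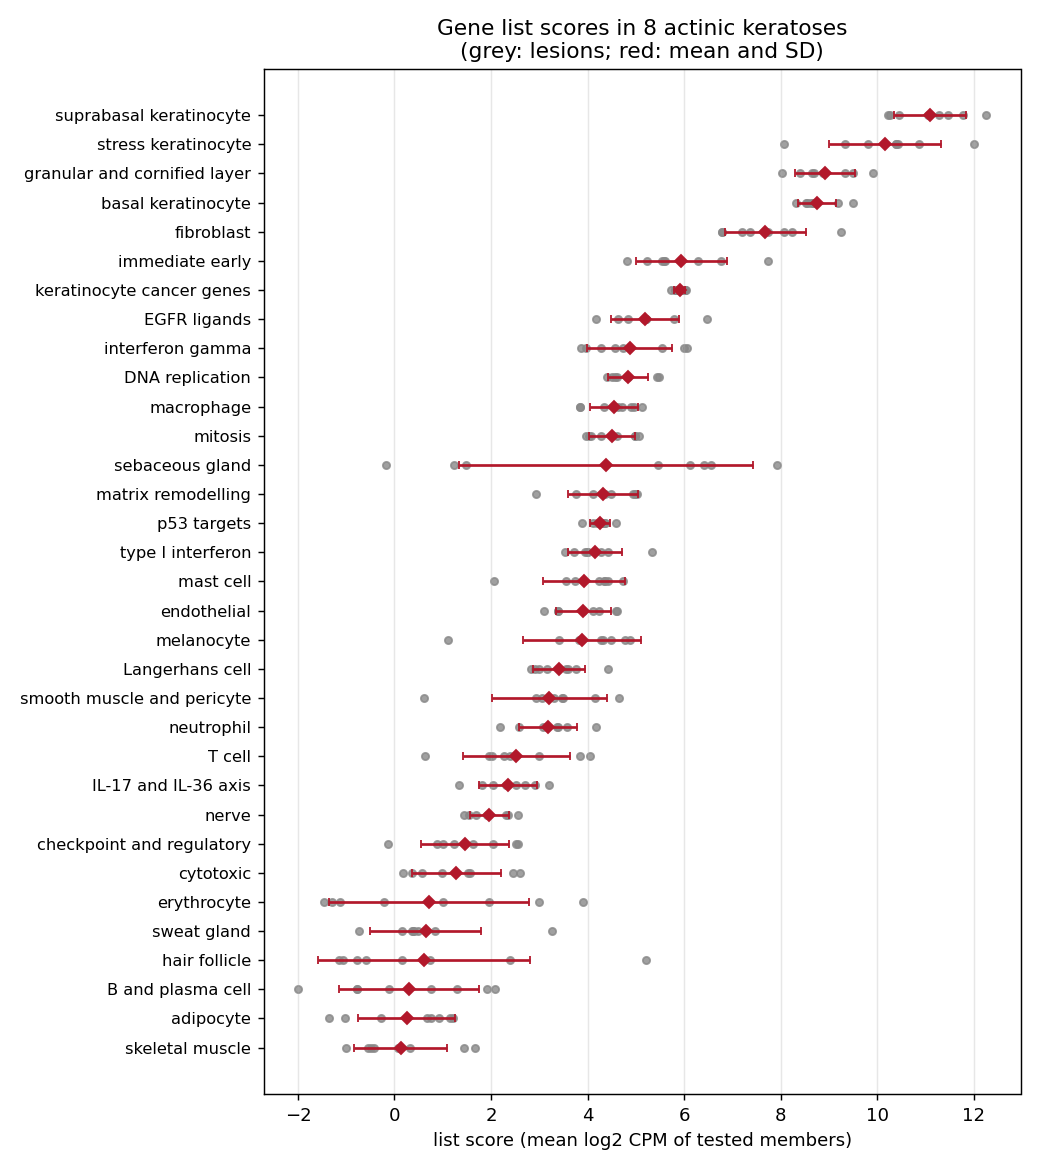
Score of each of the 33 gene lists (mean log2 CPM of its tested members, horizontal axis) in 8 lesions, with grey points for lesions and red diamonds and bars for the mean and SD. The suprabasal list lies highest at 11.10, and the sebaceous gland list spans the widest range, from -0.17 to 7.93.

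Proliferation genes were measured at moderate levels. The mitosis list scored 4.50 ± 0.48 (SD, n = 8), with TOP2A at 149.2 ± 58.3 CPM, the proliferation marker MKI67 at 97.6 ± 22.7 CPM and CCNB1 at 40.7 ± 17.2 CPM. The DNA replication list scored 4.83 ± 0.42, led by MCM4 at 117.6 ± 36.0, PCNA at 81.9 ± 31.8 and MCM3 at 68.0 ± 21.0 CPM. Targets of p53 scored 4.27 ± 0.21 and varied 1.62-fold, with CDKN1A at 186.8 ± 59.5, MDM2 at 114.9 ± 20.8 and ZMAT3 at 71.3 ± 23.0 CPM. Genes often altered in cutaneous squamous carcinoma had a mean score of 5.91 ± 0.12, which varied 1.24-fold although members varied more, CDKN2A 23.01-fold and NOTCH1 11.57-fold. They were led by FAT1 at 621 ± 231.3, NOTCH2 at 317.4 ± 81.7 and EGFR at 293.9 ± 67.6 CPM. EGFR ligands scored 5.19 ± 0.70, with EREG at 149.6 ± 112.1, EPGN at 92.9 ± 128.7 (49.6 without lesion 8) and TGFA at 77.1 ± 28.4 CPM. Matrix remodelling genes scored 4.33 ± 0.72, with TNC at 453.8 ± 219.1 and FN1 at 407 ± 568.1 CPM (211.5 CPM without lesion 7).

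Macrophage genes scored 4.55 ± 0.50 (SD, n = 8), led by LYZ at 215.9 ± 74.4, MRC1 at 50.5 ± 22.8 and CD163 at 44.4 ± 25.4 CPM. The T cell list scored 2.52 ± 1.11 and varied 10.7-fold, from 0.63 in lesion 7 to 4.05 in lesion 6, with IL7R at 44.2 ± 28.8 and CD2 at 11.2 ± 8.81 CPM. The cytotoxic list scored 1.28 ± 0.92, with CD8A at 5.43 ± 5.39, GZMK at 5.11 ± 4.99 and CST7 at 4.28 ± 2.21 CPM. Checkpoint and regulatory genes scored 1.47 ± 0.91, with HAVCR2 at 8.82 ± 1.88, TIGIT at 8.25 ± 6.50 and ICOS at 6.18 ± 5.49 CPM. B and plasma cell genes varied 16.8-fold around 0.30 ± 1.45, led by JCHAIN at 33.3 ± 31.4, CD79B at 2.44 ± 0.928 and MZB1 at 2.33 ± 2.47 CPM. The interferon gamma list scored 4.88 ± 0.88, with CD74 at 547.8 ± 213.5 and GBP1 at 70.7 ± 31.7 CPM. The type I interferon list scored 4.16 ± 0.56, with IFI27 at 133.7 ± 72.5, MX1 at 57.0 ± 26.4 and OAS2 at 35.5 ± 13.7 CPM. Neutrophil genes scored 3.19 ± 0.60, led by AQP9 at 30.2 ± 12.9, MNDA at 18.8 ± 9.26 and CXCR2 at 15.4 ± 5.34 CPM. Langerhans cell genes scored 3.40 ± 0.54, with CD207, the langerin gene, at 35.0 ± 15.8, FCER1A at 29.7 ± 10.1 and CD1A at 19.1 ± 8.18 CPM. Mast cell genes scored 3.93 ± 0.85, with CPA3 at 42.2 ± 17.6 CPM and the near-identical tryptase genes TPSB2 and TPSAB1 at 30.6 ± 16.9 and 25.2 ± 9.61 CPM.

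Transcripts of the dermis, vessels and skin appendages were present in amounts that differed between lesions. The fibroblast list scored 7.68 ± 0.84 (SD, n = 8), led by the collagen genes COL3A1 at 3149 ± 2368, COL1A2 at 1968 ± 1555 and COL1A1 at 1180 ± 1015 CPM. Sebaceous gland genes scored 4.38 ± 3.04 and varied 274-fold, with FADS2 at 512.4 ± 660.9 (304.3 without lesion 3), KRT79 at 290.2 ± 217.5 and SOAT1 at 207.2 ± 193.8 CPM. Their scores were 1.49, 1.24 and -0.17 in lesions 1, 7 and 8 and between 5.47 and 7.93 in the other lesions. Without lesion 8 the mean score was 5.03. Hair follicle genes scored 0.61 ± 2.20 and reached 5.20 in lesion 6. There the inner root sheath keratins KRT25, KRT71 and KRT27 stood at 2005, 1562 and 1458 CPM, against at most 35.0, 30.1 and 19.6 CPM in any other lesion. Without lesion 6 the hair follicle score was -0.04. Melanocyte genes scored 3.89 ± 1.22, with TYRP1 at 241.4 ± 141.9, DCT at 107.2 ± 67.7 and PMEL at 104.9 ± 61.3 CPM. The smooth muscle and pericyte list scored 3.21 ± 1.19, led by RGS5 at 74.3 ± 41.5, MCAM at 43.4 ± 15.3 and ACTA2 at 30.5 ± 13.8 CPM. Endothelial genes scored 3.92 ± 0.58, with VWF at 96.2 ± 39.3, PECAM1 at 90.3 ± 34.5 and KDR at 32.1 ± 10.97 CPM. Immediate early genes, which respond to handling and stress, scored 5.95 ± 0.94 and peaked at 7.73 in lesion 6, with FOS at 289.2 ± 379.2 (165.8 without lesion 6), JUNB at 175.2 ± 85.3 and DUSP1 at 173.8 ± 165.8 CPM. Nerve genes scored 1.97 ± 0.41, with MBP at 68.8 ± 10.7 and S100B at 9.23 ± 3.37 CPM. Erythrocyte genes scored 0.72 ± 2.07, with HBB at 26.2 ± 36.1, HBA2 at 11.2 ± 15.2 and HBA1 at 3.71 ± 5.30 CPM. Without lesion 3 these means were 15.3, 6.89 and 2.09 CPM, while the score was 1.43 because ALAS2 then fell below the count minimum. Low scores were found for the sweat gland, at 0.65 ± 1.15 with KRT77 at 42.1 ± 38.1, MUCL1 at 29.8 ± 12.8 and AQP5 at 10.9 ± 8.92 CPM, and for the adipocyte, at 0.26 ± 1.01 with PLIN4 at 16.4 ± 21.0 (9.40 without lesion 3), FABP4 at 3.18 ± 1.54 and LIPE at 1.88 ± 0.718 CPM. Skeletal muscle scored 0.13 ± 0.97 over 3 tested members, TTN at 52.1 ± 46.3, ACTA1 at 0.351 ± 0.512 (0.221 without lesion 6) and TNNT3 at 0.232 ± 0.254 CPM (0.146 without lesion 7). Without lesion 4 the sweat gland score was 2.61, and without lesion 7 the skeletal muscle score was 1.62, because members (DCD and PIP, and TNNT3) then fell below the count minimum.

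Most fixed lists differed more between lesions than random lists of equal size and expression. In 30 of 33 lists the median ratio of a gene's quasi-dispersion to its abundance trend exceeded that of 95% of 10000 random lists. The exceptions were p53 targets, at the 59.4th percentile, nerve genes, at the 72.9th, and Langerhans cell genes, just under that limit. The median ratio was 41.7 for sebaceous gland, 21.0 for erythrocyte and 15.5 for hair follicle genes, against 1.14 for p53 targets. No gene passed edgeR's test for variability beyond that of genes of like abundance after Benjamini-Hochberg adjustment over 21424 genes, where the smallest adjusted p was 0.364. An unadjusted p below 0.05 was reached by 1080 genes, against 1071 expected under the F distribution. That distribution was fitted to the spread of these same genes, so a near match follows from the fit and does not show that no gene varied. limma's variance test also called 0 genes, whereas DESeq2 marked 370 genes as dispersion outliers and edgeR without a count filter called 706. Adjusted over the list alone, edgeR called 51 list genes in 14 lists. Among them were 11 of 11 sebaceous gland genes, 6 of 11 hair follicle genes, 5 of 6 EGFR ligands and 5 of 10 melanocyte genes. That adjustment was not among the tests fixed beforehand and does not correct over the 33 lists. Its calls therefore do not replace the 0 genes of the planned test. In simulated data with the gene-to-gene spread fitted here, that edgeR test recovered 0% of 200 genes whose dispersion was raised 10-fold.

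A less demanding test, added after the values were seen, set each gene's quasi-dispersion against the abundance trend alone and called 3847 genes, 18.0% of those tested. In data simulated with the gene-to-gene spread fitted here and 200 genes changed 10-fold, it made 4080 calls, so the number called is no more than that spread gives. In every fit that left out 1 lesion, 1512 of the 3847 genes were called too. The 3847 genes included 14 of 14 stress keratinocyte genes, 10 of 10 T cell genes, 11 of 11 sebaceous gland genes, 13 of 14 matrix remodelling genes and 10 of 11 fibroblast genes. Of the squamous carcinoma genes 3 of 12 (25.0%) were called, with a median ratio of 2.15 at the 98.5th percentile of random lists, and of the p53 targets 0 of 16. Among the genes with the highest ratios, chosen after their values were seen, KRT84 had a ratio of 194.9. This member of the hair keratin family, on chromosome 12 (52377812 to 52385652, hg38), stood at 718.9 CPM in lesion 1 and at most 7.51 CPM elsewhere. KRT71 and KRT25 had ratios of 156 and 149.1, and the wax ester synthase gene AWAT2 87.6, with 147.1 CPM in lesion 3 and 0 counts in lesion 8, where 3 counts would be 0.0544 CPM. The protease inhibitor gene SPINK6 had a ratio of 98.6 and reached 293.4 CPM in lesion 8, against at most 45.7 CPM in the other lesions.

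Comparisons within each lesion asked which of a pair of genes, or of lists by score, was the higher per kilobase of transcript. A list score is a mean of log2 values, so members with few counts lower it. It does not rank lists by summed counts. The suprabasal list exceeded the basal list 8.95-fold, in 8 of 8 lesions (exact sign-flip test, two-sided p = 0.00781, adjusted p = 0.0142 over 20 comparisons). That p is the smallest that 8 lesions allow. The fold depends on the members of each list, and mean summed CPM was 35170 for suprabasal and 17560 for basal genes. The keratin pairs did not share this difference. KRT14 lay above KRT10 in 7 of 8 lesions and KRT5 above KRT1 in 5 of 8, and neither pair passed. Stress keratinocyte genes exceeded granular and cornified genes 6.18-fold, in 7 of 8 lesions (exact sign-flip p = 0.0156, adjusted p = 0.026). In lesion 7 that log2 difference was -0.05, and without lesion 7 the mean rose from 2.63 to 3.01. Leaving out any of lesions 1, 2, 3, 5 or 8 instead gave an adjusted exact p of 0.0521, and without length normalization the log2 difference was 1.24 (adjusted exact p = 0.0558). Each of the next differences held in 8 of 8 lesions, with the same exact sign-flip p = 0.00781 and adjusted p = 0.0142. By list score, T cell genes exceeded B and plasma cell genes 3.11-fold, macrophage genes exceeded T cell genes 5.05-fold, and sebaceous gland genes exceeded hair follicle genes 15.1-fold. Summed CPM gave another order in lesion 6. There the hair follicle list reached 6134 CPM, against at most 4724 CPM for the sebaceous gland list in any lesion. KRT17 exceeded the stem-cell-associated keratin KRT15 41.6-fold, and S100A9 exceeded its partner S100A8 1.47-fold. FLG exceeded LORICRIN 5.25-fold, CD4 exceeded CD8A 7.22-fold, and CDKN1A, encoding p21, exceeded CDKN2A 14.4-fold. CD4 ran from 16.7 to 41.4 CPM and stood at 28.6 CPM in lesion 7, where the T cell score was lowest. The difference of CD4 and CD8A therefore need not be a ratio of T cell types. The ligand gene CD274 exceeded its receptor gene PDCD1 6.86-fold, and KRT5 exceeded COL1A1 15.3-fold. PDCD1 had 0 counts in lesion 7, so the log2 difference of 5.90 from CD274 there depends on the prior count. With 1 lesion left out, the mean log2 difference of CD274 and PDCD1 lay between 2.33 and 2.98, against 2.78 in all lesions. Without lesion 8 the log2 difference of sebaceous minus hair follicle genes rose from 3.92 to 4.62. Without length normalization the log2 difference was -2.35 for basal minus suprabasal genes, 2.22 for T minus B and plasma cell genes, 3.78 for KRT17 minus KRT15, 5.77 for FLG minus LORICRIN, -4.86 for CDKN2A minus CDKN1A and -2.93 for COL1A1 minus KRT5, each in the same direction.

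Of the 20 comparisons, 12 passed and 8 did not. Mitosis genes lay below DNA replication genes by a log2 difference of -0.20 ± 0.26 (SD, n = 8), with an adjusted exact sign-flip p of 0.108. Without lesion 4, where it was 0.38, the difference was -0.29 and the adjusted exact p 0.026. KRT14 and KRT10 differed by 0.39 ± 0.89 (adjusted exact p = 0.344), but by 0.66 without lesion 7 (adjusted exact p = 0.024). KRT16 and KRT10 differed by 0.01 ± 1.35 (adjusted exact p = 0.984), and KRT5 and KRT1 by 0.16 ± 0.48 (adjusted exact p = 0.434). MMP1 and MMP9 differed by 1.22 ± 2.32 (adjusted exact p = 0.201), and by 1.88 without lesion 6 (adjusted exact p = 0.0481). CXCL9 and CXCL10 differed by -0.26 ± 0.97 (adjusted exact p = 0.461); without length normalization the difference was 0.96 with an adjusted exact p of 0.0142. The type I interferon list differed from the interferon gamma list by -0.36 ± 0.88 (adjusted exact p = 0.43), and Langerhans cell from melanocyte genes by 0.41 ± 1.23 (adjusted exact p = 0.434), or by -0.48 without length normalization (adjusted exact p = 0.347).

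**Figure D2:**
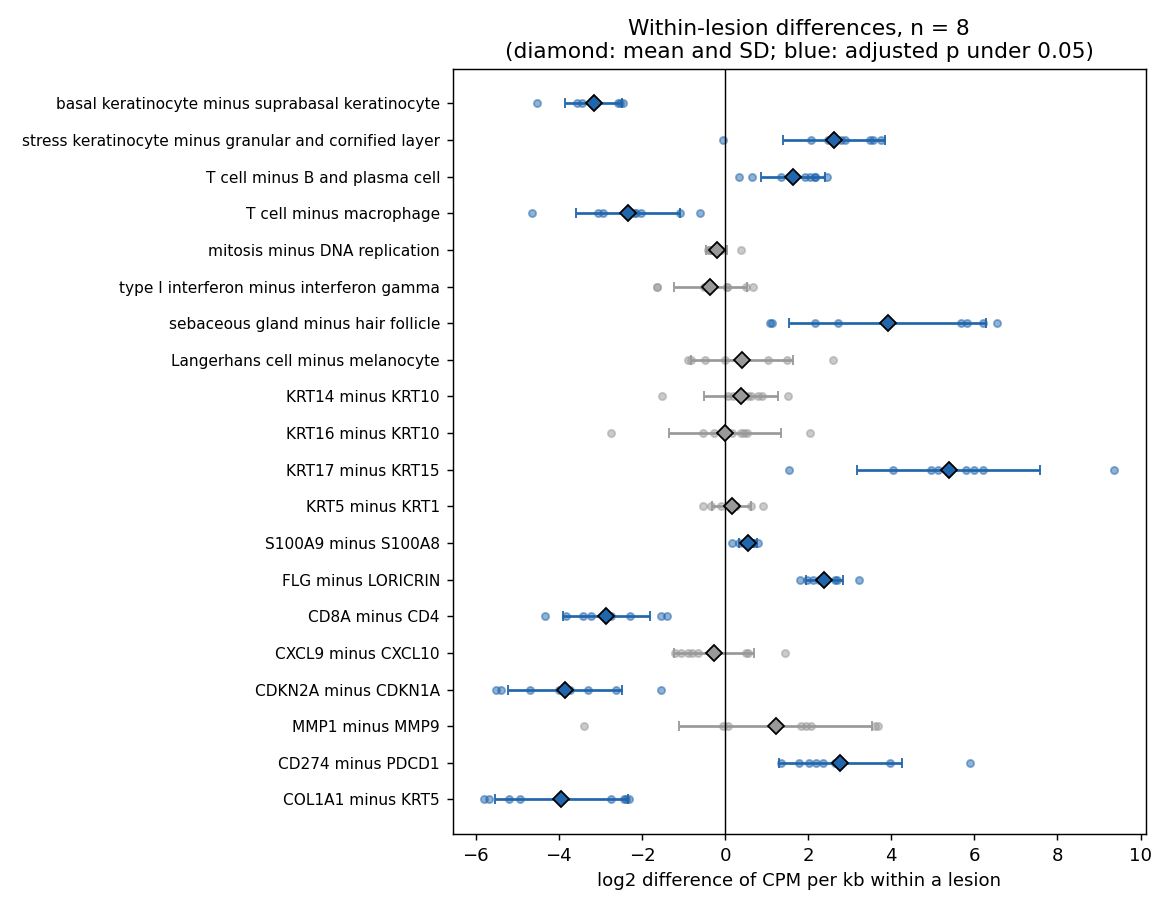
Log2 difference of CPM per kb (horizontal axis) between the pair named on the left, with points for the 8 lesions, a diamond for the mean and a bar for the SD, blue where the adjusted p was under 0.05. KRT17 minus KRT15 has the largest mean, 5.38, and lesion 7 is the only lesion below 0 for stress minus granular genes, at -0.05.

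Across lesions, cytotoxic genes rose and fell with checkpoint and regulatory genes. Pearson's r was 0.907 (exact permutation p = 0.00176, adjusted p = 0.0352 over 20 pairs, n = 8) and Spearman's rho 0.929 (exact permutation p = 0.00223, adjusted p = 0.0446). Without the 2 lesions farthest from the median, r was 0.803 (exact permutation p = 0.0431). The T cell score moved with both lists, in 2 relations that were not among the 20 pairs fixed beforehand and were not set against random lists. For the cytotoxic list r was 0.935 (exact permutation p = 0.000223, adjusted p = 0.000223 over these 2 relations, rho = 0.976). For the checkpoint list r was 0.985 (exact permutation p = 9.92e-05, adjusted p = 0.000198, rho = 0.952). Without the 2 farthest lesions these were 0.920 and 0.972. Given the T cell score, a setting added after the data were seen, r of the cytotoxic and checkpoint lists was -0.221 (adjusted permutation p = 0.722). As both lists followed the T cell score closely, little variation was left. This value therefore cannot tell whether the lists are related apart from that score. T cell genes and B and plasma cell genes had r = 0.852 (exact permutation p = 0.00699, adjusted p = 0.0484) and rho = 0.833 (exact permutation p = 0.0154, adjusted p = 0.103), and r was 0.781 without the 2 farthest lesions (exact permutation p = 0.0542). Without mitosis with DNA replication, a pair whose lesions fell into clusters, the T and B cell pair did not pass: adjusted over the remaining 19 pairs, its exact p was 0.0664. Random list pairs of equal size and expression gave a median r of 0.389 and 0.265, and the observed values lay at the 98.6th and 97.7th percentiles. Without lesion 2, 3, 4, 6, 7 or 8, neither pair passed the adjusted threshold, and without lesion 5 the T and B cell pair did not pass either (adjusted exact permutation p = 0.0615). With 1 lesion left out, r lay between 0.877 and 0.929 for the cytotoxic and checkpoint lists and between 0.738 and 0.899 for the T and B cell lists. The labels give no batch; given the library total, a setting added after the data were seen, r of the T and B cell lists was 0.886 (adjusted permutation p = 0.0618).

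**Figure D3:**
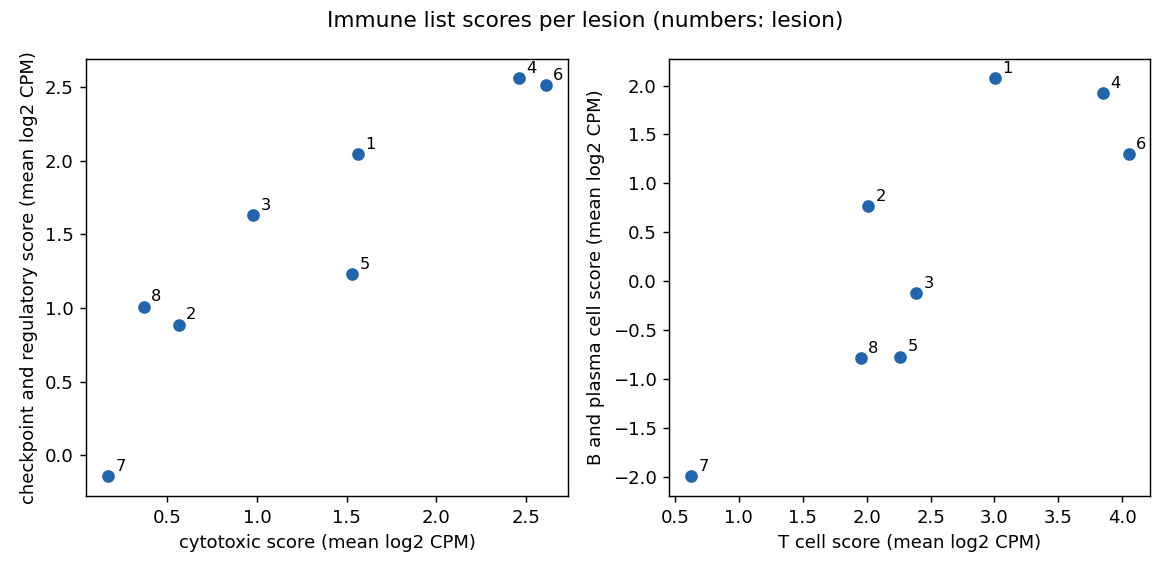
Scores (mean log2 CPM) of the checkpoint list against the cytotoxic list, and of the B and plasma cell list against the T cell list, with 1 numbered point per lesion. Lesion 7 is lowest on all 4 axes, at 0.17, -0.14, 0.63 and -1.99.

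Of the other 17 pairs with a pooled r, none passed. Interferon gamma and cytotoxic genes had r = 0.831 (exact permutation p = 0.0149, adjusted p = 0.0747) and rho = 0.810 (exact permutation p = 0.0218), and r was 0.484 without the 2 farthest lesions (exact permutation p = 0.329). The relation thus rests on them, though the narrower range alone also lowers r. Given the T cell score r was -0.197 (adjusted permutation p = 0.757). Mitosis genes had r = 0.706 with stress keratinocyte genes (exact permutation p = 0.0401, adjusted p = 0.154, rho = 0.738) and r = 0.698 with basal genes (exact permutation p = 0.0462, adjusted p = 0.154, rho = 0.476). Stress keratinocyte genes had r = 0.679 with the IL-17 and IL-36 list (exact permutation p = 0.0627, adjusted p = 0.179, rho = 0.524) and r = 0.158 with granular and cornified genes (exact permutation p = 0.723, adjusted p = 0.803, rho = 0.333). That last value lay at percentile 0.93 of random list pairs, whose median r was 0.856. Fibroblast and basal genes had r = -0.449 (exact permutation p = 0.266, adjusted p = 0.502, rho = -0.381), at percentile 0.52 of random list pairs, and r = -0.966 given the T cell score (adjusted permutation p = 0.00357). For mitosis with DNA replication genes no pooled r is given, since lesions 5 and 8 lay apart in DNA replication score. They scored 5.49 and 5.44, against at most 4.84 in the others. Their libraries were also the largest, at 73794029 and 77748599 estimated counts, against at most 63371650 in the others. Their shares of MALAT1 and NEAT1 were the lowest, at 0.24 and 0.23%, against at least 0.56%. Whether the gap in score reflects the lesions or their libraries was not tested. Within the 6 other lesions r was 0.875 (exact permutation p = 0.0181, not adjusted) and rho 0.886 (exact permutation p = 0.0333). Without the 2 farthest of these 6, r over the 4 lesions left was 0.582, and 4 lesions are too few for a test. So are lesions 5 and 8. The remaining 11 pairs had adjusted exact p of at least 0.337.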

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

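Each list score, within-lesion difference, library measure and named gene was checked for a lesion whose gap to its nearest neighbour exceeded 0.526 of the whole range. Of 181 values, 12 had such a lesion, against 9.1 expected by chance at 1 in 20, so a single value carries little weight. The tests of the patterns weighed here were chosen only after the results were seen, except the tests of transcript length and of retained introns. The design gives 1 group, so no biological explanation that it names could be tested; tissue sources were tested from marker genes.

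In lesion 1 the melanocyte score was 1.12, against 3.42 to 4.87 in the other lesions. TYRP1 stood there at 13.8 CPM against 128.7 to 438.4 CPM, and PMEL at 6.14 CPM against 46.7 to 182 CPM. In lesion 7 the mast cell score was 2.06 against 3.55 to 4.73, and TPSB2 stood at 2.24 CPM against 14.7 to 52.96 CPM. KRT77 stood in lesion 7 at 134.6 CPM against 17.7 to 40.5 CPM. PDCD1 had 0.0 CPM in lesion 7, where 3 counts would be 0.0639 CPM, against 0.254 to 1.60 CPM elsewhere. Its log2 value in lesion 7, and so the gap, was set by the prior count. The stress minus granular difference was -0.046 in lesion 7 and 2.08 to 3.76 in the others. In lesion 8 the smooth muscle and pericyte score was 0.62 against 2.94 to 4.64. In lesion 4 the sweat gland score was 3.26 against -0.73 to 0.84. Its members DCD and PIP passed the count minimum only through lesion 4, so they lower the score of the others. DCD stood at 22.8 CPM in lesion 4 and at most 0.0742 CPM elsewhere. Without DCD and PIP the mean score of the other lesions was 2.61, so the gap depends largely on these members. OAS2 stood in lesion 4 at 67.8 CPM against 24.7 to 37.3 CPM. The mitosis minus DNA replication difference there was 0.38 against -0.41 to -0.10. Outside the genes analysed, the most abundant transcript without a match took 0.68% of the library of lesion 3 (Wilson 95% interval 0.681 to 0.685%) and 0.34 to 0.63% of the others.

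Sebaceous gland genes differed 274-fold between lesions. The tables argue against sampling depth, since the median member had 15414 counts in its highest lesion. The range was at least 266-fold under each of 4 scalings, so it did not depend on the choice among them. Each scaling applies 1 factor to all genes of a library, so a small range could hardly have come out. Members rose and fell together, with a median pairwise r of 0.954, which is consistent with gland tissue being present in some samples only. That hypothesis stays open, as no histology was analysed here.

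The share of MALAT1 and NEAT1 ran from 0.23 to 3.32% of the counts in genes. It followed the share of counts of coding genes in retained-intron transcripts, with r = 0.965 (exact permutation p = 4.96e-05, adjusted p = 0.000422 over 17 relations, n = 8), rho = 1.0 and r = 0.942 without the 2 farthest lesions. It also fell with the library total, with r = -0.912 (exact permutation p = 0.00303, adjusted p = 0.00801, rho = -0.905), though without the 2 farthest lesions r was -0.754 (exact permutation p = 0.0986). More unspliced or nuclear RNA in some libraries, or something tied to depth, may account for it, and these were not separated. For transcript length bias r was 0.517 (exact permutation p = 0.192, adjusted p = 0.326) and -0.598 without the 2 farthest lesions; the first value lies between the bounds set beforehand, so it stays open with 8 lesions.

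KRT84 and KRT36 stood at 718.9 and 287.7 CPM in lesion 1, against at most 7.51 and 0.297 CPM elsewhere. Other type II hair keratins together came to 0.208% of KRT84 there, which argues against reads shared with them. The median of 5 hair and nail keratins was 0.0465% of KRT84. This argues against nail or hair shaft cells as the source only as far as those cells express these 5 keratins. KRT4 and KRT13, abundant in non-keratinized mucosa, came to 8.72% of KRT84. KRT13 alone was highest in lesion 1, at 59.3 CPM against at most 17.9 CPM elsewhere, and markers of keratinized mucosa were not tested, so oral-type epithelium stays open. The bound for this test was at first a sum under 20% of KRT84, which the value meets; that neither gene be highest in lesion 1 was added after the KRT13 level was seen.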

How the results depend on the processing

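Of the recomputed list levels, 419 moved by less than 1 SD between lesions and 10 by more. Among these, 262 and 2 came from leaving out 1 replicate. Leaving out 1 of 8 lesions cannot move a mean by 1 SD unless the tested members of a list change. Those runs therefore say little about how stable the levels are. Settings restricted to coding genes, given the library total or the T cell score, and adjusted over 19 pairs, and the trend test, were chosen after seeing the data. edgeR called 0 variable genes under both other scalings, a minimum count of 50, no robust option, coding genes only and without each replicate (0 to 0), but 706 without a filter, with 16 lists enriched, and DESeq2 marked 370 outliers, with 8 lists enriched; the cause was not tested. The trend test called 2584 to 4291 genes over its settings.

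The 12 within-lesion differences that passed numbered 11 to 13 under every setting. Without length normalization the stress minus granular difference was 1.24 (adjusted exact p = 0.0558), mitosis minus DNA replication -0.33 (adjusted exact p = 0.0361), Langerhans minus melanocyte -0.48, KRT16 minus KRT10 -0.17 and CXCL9 minus CXCL10 0.96. With 1 replicate left out they ranged from 2.47 to 3.01 for stress minus granular, -0.29 to -0.17 for mitosis minus DNA replication, -0.29 to 0.40 for KRT16 minus KRT10, 0.23 to 0.66 for KRT14 minus KRT10 and 0.87 to 1.88 for MMP1 minus MMP9. With 7 lesions fewer sign patterns exist, so the smallest p is higher.

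Of the list pairs, 2 passed in the main setting, 0 to 4 with 1 replicate left out, 4 given the fibroblast score, 1 given the library total, 1 given the T cell score, 1 with coding genes only and 1 over the 19 pairs. For T with B cell genes r was 0.865 with coding genes only (adjusted exact permutation p = 0.0565), 0.886 given the library total and 0.852 over the 19 pairs. Given the fibroblast score, r was 0.871 for matrix remodelling with stress keratinocyte genes (adjusted permutation p = 0.0341), 0.876 for the IL-17 and IL-36 list with stress genes (adjusted permutation p = 0.0341), 0.262 for T cell with macrophage and -0.659 for mitosis with T cell genes. Given the library total it was -0.106 for stress with granular genes and -0.154 for mitosis with p53 targets. Given the T cell score it was -0.221 for cytotoxic with checkpoint, -0.197 for interferon gamma with cytotoxic, -0.087 for the interferon lists, -0.161 for matrix remodelling with fibroblast and -0.966 for fibroblast with basal genes (adjusted permutation p = 0.00357). Leaving out 1 replicate gave r of 0.629 to 0.838 for mitosis with stress genes, -0.449 to 0.685 for stress with granular, -0.055 to 0.612 for basal with granular, -0.133 to 0.685 for mitosis with p53 targets and -0.347 to 0.535 for the interferon lists. It gave 0.763 to 0.969 for interferon gamma with cytotoxic, 0.877 to 0.929 for cytotoxic with checkpoint, 0.738 to 0.899 for T with B cell and -0.261 to 0.216 for T cell with macrophage genes. It gave -0.886 to -0.078 for sebaceous with granular, -0.605 to 0.559 for smooth muscle with endothelial and -0.316 to 0.360 for mitosis with T cell genes. The cause of these shifts was not tested. No paired analysis was possible because all samples form 1 group.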

Other observations

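The transcript table also separates alternative promoters, which the comparisons did not use; these genes were chosen after the data were seen. TP63, on chromosome 3, starts from an upstream promoter (189631416 to 189631516, hg38) or from one 158.1 kb downstream, which gives the form without the N-terminal transactivation domain that predominates in epidermis. The downstream starts took 99.1% ± 0.87 of its counts (SD, n = 8; 17201 to 35190 counts per lesion). LAMA3, a laminin-332 chain on chromosome 18, took 75.0% ± 10.5 of its counts from the downstream group of starts, which includes the short epidermal form, from 60.1% in lesion 7 to 88.6% in lesion 5.

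CDKN2A, on the minus strand of chromosome 9, makes the ARF transcript from its upstream starts and the p16 transcript from the downstream group, which also holds short fragments. The downstream group took 40.4% ± 19.01 of its counts (SD, n = 8). It ranged from 6.44% in lesion 7 (Wilson 95% interval 2.62 to 15.9%, 60 counts) to 65.2% in lesion 5 (61.9 to 68.5%, 806 counts). Both forms share exons, so their division is an estimate of the quantifier, and the interval covers counting error only.

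The main axis of variation among lesions, 30.9% of the variance of 18319 genes, was set against library measures, in relations chosen after the data were seen. Its r was -0.964 with the share of MALAT1 and NEAT1 (exact permutation p = 4.96e-05, adjusted p = 0.000422 over 17 relations, rho = -0.976, n = 8) and -0.949 without the 2 farthest lesions. With the library total r was 0.921 (exact permutation p = 0.000992, adjusted p = 0.00562, rho = 0.881), and 0.773 without the 2 farthest lesions (exact permutation p = 0.0778). Its r was -0.931 with the mitochondrial share (adjusted exact permutation p = 0.0057) and -0.915 with the retained-intron share (adjusted exact permutation p = 0.00581). With the share of 7SL, 7SK, RMRP and RPPH1 it was 0.895 (adjusted exact permutation p = 0.00801). Without the 2 farthest lesions these were -0.707, -0.967 and 0.837. With the slope on transcript length r was -0.634 (exact permutation p = 0.0907, adjusted p = 0.193, rho = -0.405), and 0.356 without the 2 farthest lesions. The B and plasma cell score had r = -0.571 with the library total (exact permutation p = 0.141, adjusted p = 0.266, rho = -0.619) and r = -0.386 without the 2 farthest lesions. The T cell score had r = -0.262 with the library total (exact permutation p = 0.527, adjusted p = 0.631, rho = -0.310), and the stress keratinocyte score r = 0.482 (exact permutation p = 0.232, adjusted p = 0.329, rho = 0.548), which was -0.211 without the 2 farthest lesions.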
